A study of Mus musculus with 10 samples.

How the data were processed

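RNA from 10 samples of jejunum of female mice was measured on Affymetrix whole-transcript arrays, with 1 array per sample. The labels describe 5 knockout samples and 5 controls. Both groups carried LoxP sites at both copies of Pcyt1a, and the knockouts also carried VilCreERT2, a tamoxifen-inducible Cre recombinase under the promoter of the gut epithelial gene villin. Per the labels' protocols, both groups received tamoxifen for 5 days, were fed a high fat diet for 4 days and were fasted overnight, and a 3 cm piece from the middle of the small intestine was frozen. The mice were 10 to 12 weeks old. RNA was taken up in Trizol and cleaned on columns, and biotin-labelled material was made from 400 ng of total RNA, per the labels' protocols.

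Probe set values were made with RMA in Affymetrix Expression Console 1.4.1.46, per the submitters' processing notes. RMA corrects the background, equalises the distributions of the arrays and summarises the probes of each probe set. The values the authors deposited were intensities on the linear scale, between 1.88 and 15500.2. Their log2 values fell on steps of 0.01 in 100% of cases, within 0.001 of a step, so each value carries a rounding of that size. The plan had assumed log2 values, and log2 was therefore taken first. The genome build and annotation behind the probe sets, and background or detection values, were not used here.

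Groups were taken from the sample titles, which match the genotype labels. The source labels of the controls also describe intestine without phosphatidylcholine synthesis, which goes against their titles and genotype. The series text speaks of re-feeding after the fast, whereas every sample label speaks of the fasted state. The labels name no batch, scan date, litter or collection time.

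The table held 34472 probe sets. The platform annotation gave 1 gene symbol for 23521 of them, several for 1814 and none for 9137, and only the first kind was named and tested. Of these, 23328 were matched by gene ID to the RefSeq gene table of the mouse assembly GRCm38.p6, and 0 symbols changed. Where a gene had several probe sets, which was so for 1082 genes, the probe set with the highest mean over the 10 arrays was kept. This left 22180 genes, with no intensity filter.

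Knockout and control were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on log2 values, two-sided). P-values were adjusted by the Benjamini-Hochberg method over all 22180 genes, and genes with an adjusted p under 0.05 were called. Differences are given as log2 fold change, knockout minus control, with standard error (SE). Levels are mean log2 intensity ± SD with n = 5 arrays per group. Nothing in the labels says whether the samples came from separate mice, so p-values measure the spread between these samples. For arrays there is no count of reads, and the number of arrays limits the precision.

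Lists of 29 pathways, 19 cell types and 2 positions along the gut had been written before the data were examined. Of their 1122 entries 1023 were measured, and the others were not analysed here. The red blood cell list had 3 measured members, under the minimum of 5, and was not tested. The other 49 lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 49 lists. The camera test with a correlation estimated from the arrays was run beside it, as was fry, which asks whether the members of a list move on balance in a single direction. A list score is the mean log2 intensity of the members on an array, and scores were compared by a two-sided exact permutation test over all splits of the 10 arrays, whose smallest possible p is 0.00794. List medians are medians of the members' log2 fold changes.

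The rule for naming genes was set before the data were examined. It took Pcyt1a, up to 12 called genes per direction whose groups did not overlap, up to 4 called members per list, and enzymes and transporters of the CDP-choline pathway whether or not they passed. Because 6 genes were called, the rule for list members was applied to p-values adjusted over the list alone. That extension was chosen after the number of calls was known. Arntl, Npas2, Lgr5 and Chga lie outside the rule and were named after their values were seen.

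The scripts were tested on simulated data with 200 changed genes among the 22180, over 5 runs. At a log2 change of 0.5, 37.3% of changed genes were recovered, 88.7% at a change of 1 and 98.8% at a change of 2. False calls made up 4.56% of the calls. A list shifted by 0.5 was called in 5 of 5 runs, and 0 of 240 other list tests gave a call. Genes varied independently of each other in all of these runs. On the arrays, the estimated correlation between members was 0.813 for the cell cycle list and 0.952 for smooth muscle markers. The rate of false list calls in the simulation therefore does not carry over to the list tests on the arrays. The recovery and false call rates of genes hold for independent genes with changes placed at random. They need not hold on the arrays either.

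Alternatives fixed before the data were examined were filters at a mean log2 intensity of 5 or 6, a further quantile normalisation, median centring, a variance trend with robust fitting, array weights, other choices of probe set, other thresholds, other list tests and leaving out each array. Alternatives chosen after seeing the data were the smooth muscle or Paneth cell list score as a covariate, fits without the 3 arrays highest in smooth muscle markers, fits without the 2 arrays highest in B cell markers, the exact test of list scores, and the counts over each list alone under every setting.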

Results

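The series asks what changes in the jejunum when the intestinal epithelium loses Pcyt1a. The gene encodes the enzyme that limits the rate of phosphatidylcholine synthesis through the CDP-choline pathway. Intensities of 22180 genes were compared between 5 knockout arrays, numbered 1 to 5 in the titles, and 5 control arrays, numbered 6 to 10. The median log2 intensity over these genes lay between 5.77 and 5.89 on every array. Pearson correlations between arrays, taken across genes, which are not independent replicates, were 0.982 to 0.991 within the knockouts, 0.976 to 0.987 within the controls and 0.973 to 0.989 between the groups.

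Pcyt1a was lower on every knockout array than on every control array. Its mean log2 intensity was 7.46 ± 0.25 (SD, n = 5) in knockouts and 9.39 ± 0.17 (SD, n = 5) in controls, a log2 fold change of -1.93 (SE 0.13, limma adjusted p = 9.577e-05). The knockout level was 0.262 of the control level. The knockout arrays read 7.14, 7.80, 7.30, 7.54 and 7.53, and the controls 9.55, 9.25, 9.5, 9.18 and 9.48, in the order of their numbers. The labels do not say which exons lie between the LoxP sites, so the probe set may include probes outside the deleted part. It also reads transcripts of cells in the piece that do not express villin.

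Besides Pcyt1a, 5 genes passed the threshold. Sst, which encodes the peptide hormone somatostatin, fell from 10.39 ± 0.04 to 9.19 ± 0.18 (SD, n = 5 each), a log2 fold change of -1.20 (SE 0.10, limma adjusted p = 3.483e-04). Bco1, the enzyme that cleaves beta-carotene to retinal, fell by 1.09 on the log2 scale (SE 0.15). Kcnu1, a potassium channel gene with a mean log2 intensity of 4.35 over the 10 arrays, fell by 0.89 (SE 0.12), and Scarna10, a small Cajal body RNA, fell by 0.63 (SE 0.09). Nipal2, a member of a family of magnesium transporter-like genes, rose by 1.03 (SE 0.14). These last 4 genes had an adjusted p of 0.0424. The knockout and control values of all 6 called genes did not overlap.

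**Figure D1:**
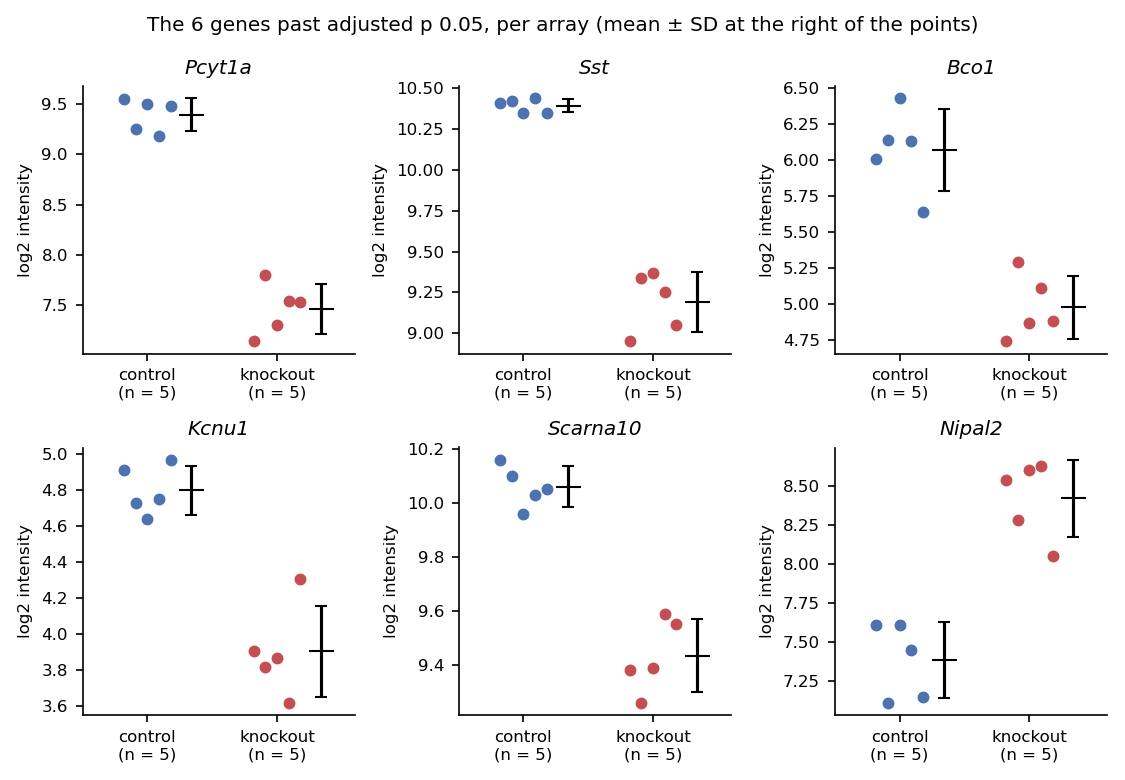
Log2 intensity (vertical axis) of the 6 called genes on each control and knockout array, with the mean and SD of each group (n = 5) at the right of its points. Pcyt1a lay between 7.14 and 7.80 in knockouts and between 9.18 and 9.55 in controls, and Nipal2 was the gene that was higher in knockouts.

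The 6 calls comprised 1 gene that was higher and 5 that were lower in knockouts. At an unadjusted p under 0.05 there were 3072 genes, 13.9% of those tested, of which 1838 were higher and 1234 lower. The groups did not overlap for 577 genes, 2.60% against the 0.794% that chance gives. The number of calls depended on single arrays. Without knockout 2, 452 genes were called, 395 higher and 57 lower. Without knockout 1, knockout 3, control 6, control 7, control 8 or control 9, 2 genes were called, and without control 10 there were 3. Pcyt1a and Sst stayed under an adjusted p of 0.05 in each of these fits, while Nipal2, Bco1, Kcnu1 and Scarna10 had adjusted p-values of 0.208 without knockout 1, for example. Median centring called 0 higher and 2 lower genes, and a further quantile normalisation 0 higher and 5 lower.

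Arrays differed in tissue makeup within both groups. The Paneth cell list score, centred on the mean of the 10 arrays, was -1.28 on knockout 2, -1.29 on control 6 and -0.77 on control 8, and between -0.12 and 0.92 on the others. Paneth cells sit at the base of the crypts. The smooth muscle score was 2.58 on control 7, 1.36 on control 9 and 0.67 on knockout 1, and between -0.89 and -0.39 on the others. The B and plasma cell score was 1.10 on control 8 and 0.80 on control 9, and between -0.36 and -0.11 on the others. Over the 10 arrays, the first principal component (26.9% of the variance) correlated with the scores of Paneth cells (Pearson r = -0.900), enterocytes (0.933) and villus tip cells (0.920). The second (17.5%) correlated with those of macrophages (-0.923) and endothelium (-0.878) and, in the other direction, distal position genes (0.794). The third (17.2%) correlated with that of smooth muscle (0.928). With the Paneth score as a covariate, a fit chosen after seeing the data, 337 genes were called, 259 higher and 78 lower.

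Of the 49 lists, 20 were called with the preset correlation, 11 higher and 9 lower in knockouts. With an estimated correlation 0 were called, against 7 at an unadjusted p under 0.05. By fry 4 were called, namely enteroendocrine cells, tuft cells, gut hormones and phospholipid remodelling. By the exact permutation test of list scores 11 lists had an unadjusted p under 0.05 and 0 passed after adjustment, with a smallest adjusted p of 0.0778. That value belonged to lists at the smallest possible p of 0.00794, which could pass only if more lists reached it. Failing the test after adjustment is therefore weak evidence against those lists. Some other called lists had an unadjusted exact permutation p above 0.05, which this limit does not explain. They were smooth muscle and goblet cells (0.532 each), fibroblasts (0.421), B cells (0.302), crypt stem cells (0.198), villus tip (0.151) and phospholipid remodelling (0.143). Interferon response and proximal position (0.111 each), the unfolded protein response (0.0952) and macrophages (0.0635) were also among them.

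**Figure D2:**
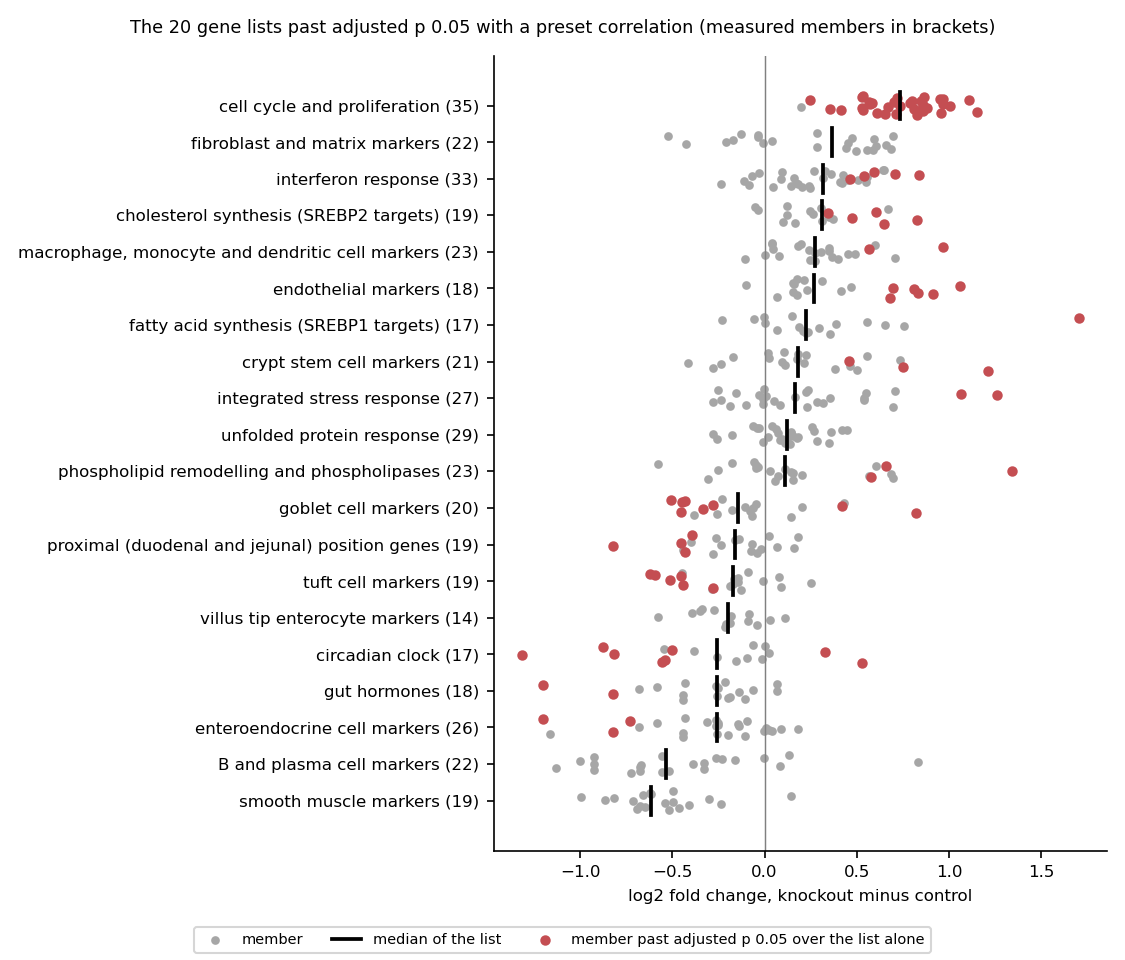
Log2 fold changes, knockout minus control (horizontal axis), of the measured members of the 20 called lists, with the number of members in brackets. Each point is a gene, red points passed an adjusted p of 0.05 over the list alone, and black bars are list medians, from 0.73 for the cell cycle list to -0.62 for smooth muscle markers.

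The cell cycle list was called higher in knockouts with the preset correlation. All 35 measured members had a positive log2 fold change, and 34 passed when adjusted over the list alone, although 0 passed over all genes tested. The list median was 0.73 (camera adjusted p = 1.904e-26; adjusted p = 0.310 with an estimated correlation). Ccna2, the cyclin of S phase and mitotic entry, was higher by 1.15 (SE 0.28), the mitotic kinase Plk1 by 1.11 (SE 0.26), the spindle motor Kif11 by 1.00 (SE 0.21) and the replicative helicase subunit Mcm3 by 0.97 (SE 0.23). Their p-values adjusted over all genes lay between 0.111 and 0.130. The list score was 7.73 ± 0.39 in knockouts and 7.00 ± 0.30 in controls (SD, n = 5 each; exact permutation p = 0.0317, adjusted 0.173 over the 49 lists). Among the knockouts it was lowest on knockout 2, and among the controls on control 6, the arrays with the lowest Paneth scores. The cell cycle (-0.904) and crypt stem cell (-0.865) scores correlated with the first component, as the Paneth score did. The count was 31 to 35 with any 1 array left out and 22 without the 3 arrays highest in smooth muscle. In the crypt stem cell list, 3 of 21 members rose when adjusted over the list alone (median 0.18, camera adjusted p = 0.00874; adjusted p = 0.743 with an estimated correlation). These were the water channel Aqp4 (1.21, SE 0.23), the adhesion receptor Cd44 (0.75, SE 0.14) and the RNA-binding protein Msi1 (0.46, SE 0.11). The stem cell gene Lgr5, named after its value was seen, was at -0.42 (SE 0.19) and did not pass. The crypt list count was 7 without knockout 2, when its median was 0.29. The camera call of that list was lost without knockout 4 (median 0.12, adjusted p = 0.0779) and without control 6 (0.062, adjusted p = 0.149), and with only genes at a mean log2 intensity of at least 5 (adjusted p = 0.0550) or 6 (adjusted p = 0.123). The crypt list median was 0.10 with the Paneth covariate and 0.34 without the 3 arrays highest in smooth muscle.

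**Figure D3:**
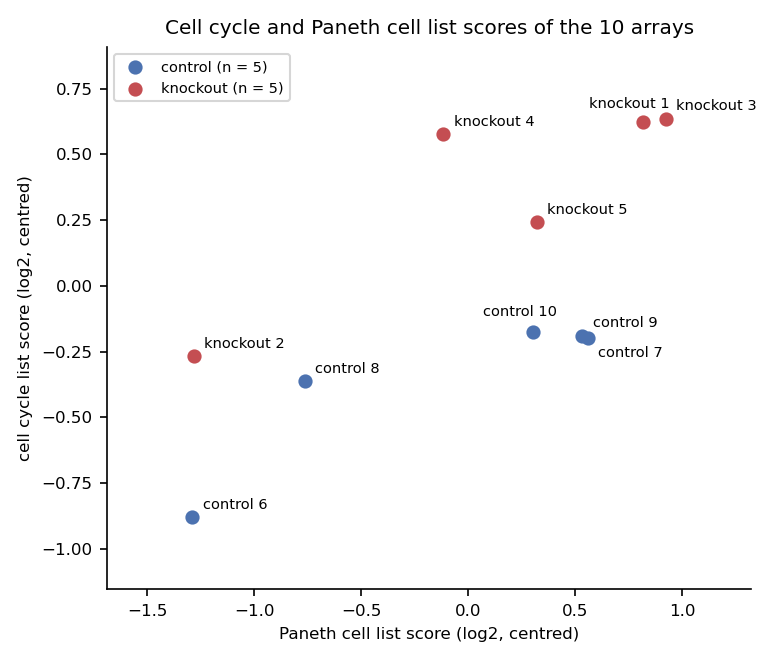
Cell cycle list score against Paneth cell list score of the 10 arrays, both as mean log2 intensity minus the mean over arrays, with knockouts in red and controls in blue. Knockout 2 had a cell cycle score of -0.27 at a Paneth score of -1.28, and the other 4 knockouts lay between 0.24 and 0.64 on the cell cycle axis, above the 5 controls at -0.88 to -0.18.

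The lists of SREBP2 and SREBP1 targets were called higher in knockouts with the preset correlation (adjusted p = 0.447 and 0.290 with an estimated correlation), and 0 members passed over all genes. In the cholesterol synthesis list, made of targets of the transcription factor SREBP2, 17 of 19 members had positive values and 5 rose when adjusted over the list alone (median 0.31, camera adjusted p = 8.997e-07; adjusted p = 0.447 with an estimated correlation). Farnesyl diphosphate synthase Fdps was higher by 0.83 (SE 0.16), Cyp51 by 0.65 (SE 0.21), Nsdhl by 0.61 (SE 0.13) and Hsd17b7 by 0.48 (SE 0.13). The cholesterol count was 10 without knockout 2, 3 without knockout 3, knockout 4, knockout 5 or control 7, and 2 without knockout 1 or control 6. It was 2 with a further quantile normalisation, 3 with the smooth muscle covariate and 0 without the 3 arrays highest in smooth muscle. The first principal component of the arrays correlated with the scores of cholesterol synthesis (Pearson r = -0.771) and SREBP1 targets (-0.629), as with those of Paneth cells (-0.900) and, in the other direction, enterocytes (0.933). On knockout 2, the knockout lowest in Paneth markers, the cholesterol score lay 0.905 of the way from the other knockouts to the controls, and the list median with the Paneth covariate was 0.25. In the fatty acid synthesis list of SREBP1 targets, 1 of 17 members rose (median 0.22, camera adjusted p = 0.00120; adjusted p = 0.290 with an estimated correlation). That gene was Scd1, which makes monounsaturated fatty acids, at 1.71 (SE 0.37, adjusted p = 0.121 over all genes). The score of SREBP1 targets was 8.14 ± 0.13 in knockouts and 7.82 ± 0.12 in controls (SD, n = 5 each). Its exact permutation p was 0.00794, the smallest possible (adjusted 0.0778), against 0.0317 (adjusted 0.173) for cholesterol synthesis. The lowest knockout, knockout 2 at 7.972, lay just above the highest control, control 7 at 7.968. The count for SREBP1 targets was 7 without knockout 2 and 3 without control 7, 3 with array weights, 4 with the smooth muscle covariate, 6 with the Paneth covariate and 2 without the 3 arrays highest in smooth muscle. Scd1 was also the 1 member of the list of targets of the nuclear receptor LXR that passed over the list alone, and that list of 11 was not called (median -0.004, against a mean of 0.16 and a camera direction of higher, adjusted p = 0.270).

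Other enzymes of phosphatidylcholine and phosphatidylethanolamine synthesis gave no further call. Of 17 measured members, Pcyt1a fell, and the list median was -0.03 (camera adjusted p = 0.655). Pcyt1b, the second gene for the same step, was at -0.35 (SE 0.12, adjusted p = 0.240) with a mean log2 intensity of 4.51. Choline kinase Chka was at 0.24 (SE 0.11), the choline transporter-like Slc44a3 at 0.25 (SE 0.10), Pcyt2 of the ethanolamine branch at -0.07 (SE 0.10) and Pemt, which methylates phosphatidylethanolamine, at 0.18 (SE 0.15). Chpt1 was at -0.13 (SE 0.24), Selenoi at 0.01 (SE 0.11) and Pisd at -0.13 (SE 0.10), and 95% intervals of all these genes other than Pcyt1a, Pcyt1b and Slc44a3 included 0. In the list of phospholipid remodelling enzymes and phospholipases, 3 of 23 members rose when adjusted over the list alone (median 0.11, camera adjusted p = 0.0112; adjusted p = 0.263 with an estimated correlation; fry adjusted p = 0.0196). They were the lysophospholipid acyltransferase Mboat1 (1.34, SE 0.33), the cytosolic phospholipase Pla2g4a (0.66, SE 0.17) and the acyltransferase Agpat5 (0.58, SE 0.16). Their count was 0 without knockout 1, knockout 3 or control 6, and 1 without knockout 4 or control 10. The list median was 0.04 without knockout 2, 0.17 without control 9 and 0.05 without the 3 arrays highest in smooth muscle. The camera call was lost with only genes at a mean log2 intensity of at least 5 (adjusted p = 0.0508) or 6 (adjusted p = 0.0922), where 6 members passed over the list alone, and with a further quantile normalisation (adjusted p = 0.0616). The score of this list correlated with the first component (r = -0.862), as Paneth scores did (-0.900) and enterocyte scores in the other direction (0.933). The count was also 6 with median centring and with a variance trend, 5 with the Paneth covariate, and 0 without the 3 smooth muscle arrays or the 2 arrays highest in B cell markers.

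Lists for the handling of dietary lipid were not called. The median was 0.04 for fatty acid and cholesterol uptake (16 members, mean -0.05, camera adjusted p = 0.994), -0.002 for triglyceride synthesis and lipid droplets (24 members, camera adjusted p = 0.923) and -0.04 for chylomicron assembly (17 members, camera adjusted p = 0.926). It was -0.01 for fatty acid oxidation and targets of the peroxisome proliferator receptors (28 members, mean 0.01, camera adjusted p = 0.923) and -0.05 for bile acid transport and signalling (13 members, camera adjusted p = 0.770). In all 4 of the first lists the camera direction was higher, against the sign of the median in the triglyceride, chylomicron and fatty acid oxidation lists and of the mean in the uptake, triglyceride and chylomicron lists. In the chylomicron list Apoc3, an apolipoprotein that slows lipoprotein clearance, fell by 0.43 (SE 0.10, adjusted p = 0.0188 over the list alone). It missed that threshold without knockout 1, knockout 3, knockout 4, control 6 or control 8, when the count was 0.

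The enteroendocrine marker and gut hormone lists were called lower in knockouts with the preset correlation. In the enteroendocrine marker list 21 of 26 members had negative values and 3 fell when adjusted over the list alone, of which Sst also passed over all genes (median -0.26, camera adjusted p = 1.058e-05; adjusted p = 0.163 with an estimated correlation; fry adjusted p = 0.0137). Gip, the incretin of the upper small intestine, fell by 0.82 (SE 0.14, adjusted p = 0.0728 over all genes) and the granule protein Scg3 by 0.73 (SE 0.18). The general marker chromogranin A (Chga), named after its value was seen, was at -0.10 (SE 0.13). The list score was 6.57 ± 0.09 in knockouts and 6.89 ± 0.13 in controls (SD, n = 5 each; exact permutation p = 0.00794, the smallest possible, adjusted 0.0778). The gut hormone list shares 12 of its 18 genes with that list. Its called members over the list alone were Sst and Gip (median -0.26, camera adjusted p = 4.002e-05; adjusted p = 0.163 with an estimated correlation). Both list calls held with any 1 array left out. The hormone median was -0.43 with only genes at a mean log2 intensity of at least 6 and -0.16 without the 3 arrays highest in smooth muscle, and 5 enteroendocrine markers passed over the list alone with the Paneth covariate. The enteroendocrine (0.718) and hormone (0.731) scores correlated with the second component, as did the distal position score (0.794), against macrophage (-0.923) and endothelial (-0.878) scores.

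The list of tuft cells, the chemosensory cells of the epithelium, was also called lower. Of 19 members 16 had negative values, and 6 fell when adjusted over the list alone (median -0.17, camera adjusted p = 2.724e-05; adjusted p = 0.163 with an estimated correlation; fry adjusted p = 0.0196). Sh2d6 fell by 0.62 (SE 0.13), Rgs13 by 0.59 (SE 0.17), Lrmp by 0.51 (SE 0.15) and Pou2f3, the transcription factor that tuft cells need, by 0.45 (SE 0.11). The tuft list score was 6.48 ± 0.06 in knockouts and 6.70 ± 0.10 in controls (SD, n = 5 each; exact permutation p = 0.00794, adjusted 0.0778). The tuft score correlated with the first component (r = 0.847), as enterocyte (0.933) and villus tip (0.920) scores did, and Paneth scores in the other direction (-0.900). The count was 5 to 8 with any 1 array left out and 3 without the 2 arrays highest in B cell markers. The goblet score correlated with the second component (r = 0.704). In the goblet cell list 6 of 20 members fell and 2 rose when adjusted over the list alone (median -0.14, camera adjusted p = 0.00936; adjusted p = 0.743 with an estimated correlation). The tryptase Tpsg1 fell by 0.51 (SE 0.15), Clca1 by 0.45 (SE 0.13) and Sytl2 by 0.45 (SE 0.11), and the chemokine Ccl9 rose by 0.82 (SE 0.25). The goblet list call was lost without knockout 2 (median -0.04), knockout 4 (-0.10) or control 9 (-0.10), the median was -0.22 without knockout 3, and 3 members fell without control 10. That call was also lost with the smooth muscle covariate (adjusted p = 0.0604), without the 3 arrays highest in smooth muscle (median -0.09, 2 members lower) and without the 2 highest in B cell markers (adjusted p = 0.132). The count of 2 that rose was 0 without knockout 1, knockout 3 or control 10, and 1 without knockout 2, knockout 5, control 6 or control 8, with a further quantile normalisation, with array weights or without the 3 smooth muscle arrays.

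Of the absorptive cell lists, villus tip markers were called lower. The enterocyte list was not called (20 members, median -0.10, camera adjusted p = 0.0529), though it was past the threshold in 8 of 14 other settings and without any 1 of knockout 2, knockout 4, knockout 5, control 7, control 9 or control 10. The villus tip list was called lower with 0 of 14 members passing over the list alone (median -0.20, camera adjusted p = 0.0189; adjusted p = 0.743 with an estimated correlation). That call was lost without knockout 1 (median -0.14), knockout 3 (-0.15) or control 6 (-0.12), and without the 2 arrays highest in B cell markers (adjusted p = 0.0599). Brush border hydrolases (22 members, median -0.06, camera adjusted p = 0.128) and sugar, peptide and amino acid transporters (22 members, median -0.09, camera adjusted p = 0.398) were not called, and Slc2a1 of the latter passed over the list alone at 0.42. Slc2a1 has 2 probe sets, at 0.12 and 0.42, and was at 0.27 with their mean. The transporter count of 1 was 0 with that mean, with a further quantile normalisation, without the 3 arrays highest in smooth muscle and without the 2 highest in B cell markers. It also changed in 8 of the 10 fits without 1 array, to 3 without knockout 2 for example and to 0 without knockout 1. The brush border list was called lower with only genes at a mean log2 intensity of at least 5 (adjusted p = 0.0485) or 6 (adjusted p = 0.0170), with a further quantile normalisation (adjusted p = 0.0227), without knockout 2 (adjusted p = 0.0380) and without control 7 (adjusted p = 0.0403). The list of the proximal small intestine was called lower (4 of 19 when adjusted over the list alone, median -0.16, camera adjusted p = 0.00491; adjusted p = 0.602 with an estimated correlation), namely Gip, lactase Lct (-0.45, SE 0.13), Apoc3 (-0.43, SE 0.10) and Tff2 (-0.40, SE 0.09). Their count was 2 without the 3 arrays highest in smooth muscle or the 2 highest in B cell markers, and their score correlated with the first component (r = 0.867), as that of enterocytes did (0.933). Genes of the distal small intestine were not called (18 members, median -0.07, camera adjusted p = 0.398), and the 1 that passed over the list alone was the receptor Cubn at -0.91. Cubn missed that threshold in 6 of 13 other settings and without any 1 of knockout 1, knockout 3, knockout 4, control 6, control 8, control 9 or control 10. The Paneth cell list was not called either (15 members, median 0.36, camera adjusted p = 0.390), and the median was -0.02 without control 6 and 0.55 without knockout 2, when the list was called. It was also called with the smooth muscle covariate (adjusted p = 0.0252) and without the 3 arrays highest in smooth muscle (adjusted p = 0.0224).

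**Figure D4:**
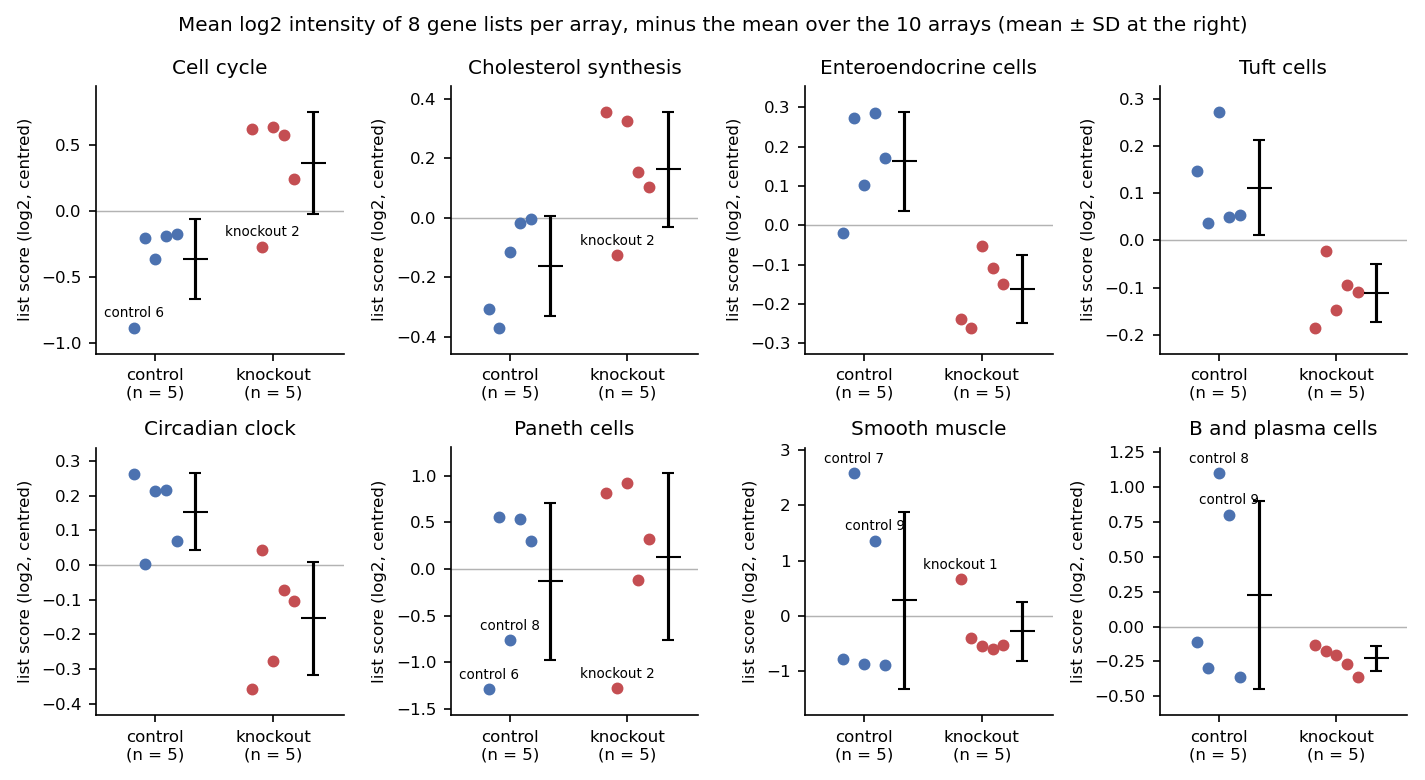
List scores (mean log2 intensity of the members minus the mean over the 10 arrays, vertical axis) of 8 lists on each array, with the mean and SD of each group (n = 5) at the right. The 5 knockouts lay below the 5 controls for enteroendocrine and tuft cells, knockout 2 lay among the controls for the cell cycle and cholesterol synthesis, and control 7 stood highest for smooth muscle.

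Members of the circadian clock list moved in both directions, and 0 passed over all genes tested. The labels give no collection time, so a difference in it between the groups cannot be excluded. Of 17 members of the circadian clock list 6 fell and 2 rose when adjusted over the list alone (median -0.26, camera adjusted p = 0.00510; adjusted p = 0.310 with an estimated correlation). The output transcription factor Dbp fell by 1.32 (SE 0.41), Per3 by 0.87 (SE 0.24), Hlf by 0.81 (SE 0.19) and Bhlhe40 by 0.55 (SE 0.13). The 2 that rose, named because they ran against the list, were the activators Arntl (0.53, SE 0.14) and Npas2 (0.33, SE 0.12). The number that fell was 3 without knockout 1, knockout 3, control 6 or control 8, and 0 without the 2 arrays highest in B cell markers. The number that rose was 1 without knockout 1, knockout 3, knockout 5, control 6, control 7 or control 8. The median was -0.13 without knockout 1, -0.17 without control 6 and -0.44 with only genes at a mean log2 intensity of at least 6. The list call was lost without the 2 B cell arrays (median -0.29, adjusted p = 0.0571), when 0 members rose, and 1 rose with a further quantile normalisation. The clock score correlated with the first component (r = 0.867), as enterocyte scores did (0.933) and Paneth scores in the other direction (-0.900), and on knockout 2 it was 7.5, among the controls at 7.46 to 7.72.

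Among stress pathways, the integrated stress response list was called higher, with 2 of 27 members rising when adjusted over the list alone (median 0.16, camera adjusted p = 0.00631; adjusted p = 0.491 with an estimated correlation). They were Psat1 (1.26, SE 0.28) and Shmt2 (1.07, SE 0.23), enzymes of serine and one-carbon metabolism. The count was 6 without knockout 2 or control 7 and 4 without control 8, when the median was 0.08. The call was lost with only genes at a mean log2 intensity of at least 5 (median 0.08, adjusted p = 0.0992) or 6 (0.08, adjusted p = 0.301). The median was 0.10 with the Paneth covariate, without the 3 arrays highest in smooth muscle and without the 2 highest in B cell markers, and the count was 6 with array weights or either covariate and 4 without the 2 B cell arrays. The score correlated with the first component (r = -0.902), as Paneth scores did (-0.900) and enterocyte scores in the other direction (0.933), and on knockout 2 it was 6.79, among the controls at 6.63 to 6.89. The unfolded protein response list was called with 0 of 29 members passing over the list alone (median 0.12, camera adjusted p = 0.00350; adjusted p = 0.722 with an estimated correlation; median 0.08 without control 7). That call was lost with only genes at a mean log2 intensity of at least 6 (adjusted p = 0.0774) and with a further quantile normalisation (median 0.08, adjusted p = 0.0957), and its score correlated with the first component (r = -0.686). The p53 target list was not called (21 members, median -0.10, camera adjusted p = 0.291, and 0.0462 with only genes at a mean log2 intensity of at least 6), and its 1 member past the threshold over the list alone, Aen, was higher by 0.38 (SE 0.08), and missed it without the 3 arrays highest in smooth muscle. The interferon response list was called higher, with 5 of 33 rising when adjusted over the list alone (median 0.32, camera adjusted p = 8.997e-07; adjusted p = 0.602 with an estimated correlation). Oas2 was higher by 0.84 (SE 0.18), Oasl2 by 0.71 (SE 0.16), Rsad2 by 0.59 (SE 0.17) and Mx2 by 0.54 (SE 0.13). The interferon score correlated with the second component (r = -0.863), as those of macrophages (-0.923) and endothelium (-0.878) did, 2 lists that were also called higher. The interferon count was 14 without control 6, 9 without knockout 5 and 3 without knockout 3, knockout 4, control 7, control 9 or control 10. It was 0 without the 2 arrays highest in B cell markers and 0 without the 3 highest in smooth muscle, and the median was 0.21 without knockout 2. The interferon count was 12 with the Paneth covariate and 3 with a further quantile normalisation or the smooth muscle covariate.

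Of the lists for cells outside the epithelium, 5 were called with the preset correlation and 0 with an estimated one. Endothelial markers were called higher, with 6 of 18 rising when adjusted over the list alone (median 0.27, camera adjusted p = 1.206e-06; adjusted p = 0.387 with an estimated correlation). The largest were Plvap (1.06, SE 0.31), Emcn (0.92, SE 0.28), Eng (0.83, SE 0.21) and Kdr (0.81, SE 0.29). The count was 3 without knockout 2 or control 10 and 1 without the 3 arrays highest in smooth muscle, and the median was 0.16 without control 9. It was 0.70 with only genes at a mean log2 intensity of at least 6, 0.15 without the 3 smooth muscle arrays and 0.12 without the 2 arrays highest in B cell markers, and the list was called in all of these. Macrophage, monocyte and dendritic cell markers were called higher, with Ly6c2 (0.97, SE 0.22) and Itgam (0.57, SE 0.12) passing among 23 over the list alone (median 0.28, camera adjusted p = 3.633e-06; adjusted p = 0.567 with an estimated correlation). That median was 0.18 without knockout 2 or control 9, and the count was 9 with the Paneth covariate and 1 without the 3 smooth muscle arrays. Fibroblast and matrix markers were called higher with 0 of 22 members passing over the list alone (median 0.36, camera adjusted p = 0.00407; adjusted p = 0.743 with an estimated correlation). Their call was lost without knockout 1 (adjusted p = 0.0874) and without the 2 arrays highest in B cell markers (adjusted p = 0.0640), and the median was 0.55 without control 7 and 0.17 without control 10. B and plasma cell markers (0 of 22, median -0.54, camera adjusted p = 6.442e-04; adjusted p = 0.743 with an estimated correlation) and smooth muscle markers (0 of 19, median -0.62, camera adjusted p = 0.0235; adjusted p = 0.83 with an estimated correlation) were called lower. The B cell median was -0.24 without control 8 and -0.34 without control 9, and -0.02 with an adjusted p of 0.792 without both. The B cell call was also lost with only genes at a mean log2 intensity of at least 6 (median -0.44, adjusted p = 0.0521). The smooth muscle call was lost without control 7 (median -0.01), control 9 (-0.31) or any 1 of knockouts 2 to 5 (-0.57 to -0.51). Without control 7, control 9 and knockout 1 its median was 0.38 (camera adjusted p = 2.042e-08).

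The remaining lists were not called with all 10 arrays, no filter and no covariate. Energy metabolism lists had medians of 0.08 for oxidative phosphorylation (29 members, camera adjusted p = 0.0602, and past the threshold in 5 of 14 other settings and in 5 of the 10 fits without 1 array, for example 0.0394 with median centring and 0.0189 without knockout 5) and 0.04 for glycolysis and gluconeogenesis (19 members, adjusted p = 0.289), and in the latter 2 members passed over the list alone, the glucose transporter Slc2a1 (0.42) and the pyruvate kinase Pklr (0.33). That count was 0 without control 7, and Pklr also missed it without knockout 2, knockout 4 or control 9, and both genes with a further quantile normalisation, without the 3 smooth muscle arrays and without the 2 B cell arrays. Defence and immune lists had medians of 0.16 for antimicrobial genes (22 members, adjusted p = 0.162, but called without control 7, with the smooth muscle covariate and without the 3 smooth muscle arrays), -0.12 for T cells and intraepithelial lymphocytes (24 members, adjusted p = 0.249, but called without knockout 2 and without the 3 smooth muscle arrays) and 0.06 for cytokines and chemokines (28 members, adjusted p = 0.426). The median was -0.01 for granulocytes and mast cells, whose mean was 0.03 (27 members, adjusted p = 0.992), and -0.05 for MHC class II genes, whose camera direction was higher (11 members, adjusted p = 0.994). Among other lists, the median was -0.06 for iron and haem handling (11 members, adjusted p = 0.972), where the transferrin receptor Tfrc passed over the list alone at 0.76. Tfrc missed that threshold in 3 of 13 other settings and without any 1 of knockout 1, knockout 3, knockout 4, knockout 5, control 6, control 9 or control 10. The median was -0.02 for tight and adherens junctions, whose mean was 0.01 (20 members, adjusted p = 0.992), where the pore-forming claudin Cldn2 passed over the list alone at 1.05 (adjusted p = 0.0688 over all genes). Regenerating epithelium (15 members, median -0.03, adjusted p = 0.994), with Clu passing over the list alone at -1.37 (-0.90 without the 2 B cell arrays, control 8 and control 9, which hold its highest values at 8.66 and 8.15), and xenobiotic metabolism (28 members, median -0.02, adjusted p = 0.994), with Gsr at 0.67 and Ces2a at -0.60 passing over the list alone, had a camera direction of higher against negative medians. Gsr missed the threshold in 3 of 13 other settings and in 8 of the 10 fits without 1 array, all but those without knockout 2 or control 10, and Ces2a without the 3 smooth muscle arrays, while 3 members fell without knockout 2. A camera direction of higher against a negative median also held for Golgi and secretory glycosylation (22 members, median -0.01, mean 0.02, adjusted p = 0.994). Medians were -0.002 for lysosome and autophagy (25 members, adjusted p = 0.992), -0.15 for enteric neurons and glia (19 members, adjusted p = 0.0968, but called at a mean log2 intensity of at least 5, without knockout 1, control 6 or control 8, with the Paneth covariate and without the 2 B cell arrays), -0.07 for pancreatic acinar cells (19 members, adjusted p = 0.737) and -0.06 for adipocytes and mesenteric fat (14 members, adjusted p = 0.766).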

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

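The tests of incomplete deletion, of crypt, muscle and epithelial content for the cell cycle and hormone lists, and of position along the gut were chosen only after the result was seen. So was the setting with the Paneth covariate. So was the count of splits for the setting without knockout 2, which had been fixed beforehand, as 1 of 10 that each leave out an array, and was singled out after its count was seen. An array was singled out when its gap to the nearest other array of its group, divided by the range of the group, passed the 95% critical value for 5 samples. This happened in 13 of 248 groups of values tested, and chance alone would give about 12.4.

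In the knockouts, knockout 5 stood apart with the lowest Oas2 (6.63, nearest 7.17, gap 0.818 of the range) and the lowest Pla2g4a (6.86, nearest 7.35, gap 0.860). Knockout 3 had the lowest Slc5a7 (3.85, nearest 4.31, gap 0.807). Knockout 2 had the highest Bhlhe40 (9.35, nearest 9.19, gap 0.762) and the lowest Tfrc (8.72, nearest 9.43, gap 0.740). Knockout 1 had the highest smooth muscle score (7.68, nearest 6.62, gap 0.838) and the highest enteric neuron and glia score (5.40, nearest 5.21, gap 0.726). In the controls, control 6 had the lowest Plk1 (6.43, nearest 7.40, gap 0.752), Kif11 (6.54, nearest 7.29, gap 0.833), Mcm3 (5.75, nearest 6.56, gap 0.764) and cell cycle score (6.48, nearest 7.00, gap 0.737). It also had the highest triglyceride and lipid droplet score (8.36, nearest 8.24, gap 0.742). Control 10 had the lowest oxidative phosphorylation score (9.55, nearest 9.70, gap 0.750).

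Of 100 splits of the 10 arrays into 5 and 5, the real split included, 2 called as many genes. Such a count was rare, but the share depends on which splits were drawn and covers the count, not each gene. Pcyt1a is deleted by design, which gives the real split a call in advance. Nipal2, Bco1, Kcnu1 and Scarna10 missed the threshold with median centring (limma adjusted p = 0.0649), so chance stays open for them. The highest other split, of knockouts 1, 3 and 5 with controls 9 and 10, called 114 genes, which points to a structure of the samples other than genotype. The distal position score was 8.26 to 8.82 on these 5 arrays and 7.96 to 8.15 on the others. The proximal score was 8.18 to 8.38 against 8.49 to 8.73, so scores of position along the gut separate this split. Goblet scores did so too (9.57 to 9.83 against 9.15 to 9.48). So did scores of phospholipid remodelling (8.12 to 8.38 against 7.74 to 7.98) and the unfolded protein response (9.24 to 9.40 against 9.07 to 9.22). Both of these lists were called higher in knockouts. Scores of fatty acid and cholesterol uptake, fatty acid oxidation, glycolysis and iron handling also separated this split, and were lower on these 5 arrays. The cause was not tested. For the 20 called lists chance cannot be excluded, because 15 of the 100 splits called as many, and the highest other called 29.

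Without knockout 2, 452 genes were called, and with each split given the left-out array that calls most, 4 of 100 splits reached that count, too near the limit of 5 to exclude chance safely, since the share depends on which splits were drawn. The highest other split called 687, and the 3 that reached the count all set knockouts 1, 3, 4 and 5 with 1 control against the rest, knockout 2 among them. These splits keep most of the genotype contrast, so they do not stand for chance alone and cannot separate it from genotype. With the Paneth covariate 337 genes were called, as many as in 1 of 100 splits, with 8 in the highest other, but chance cannot be excluded from that, because the choice of the covariate was not repeated in the splits. Of the 452 genes, 54.2% were also called with the covariate, but this decides nothing on crypt content of the tissue piece, because both fits take weight from knockout 2 and share the other arrays. The Pcyt1a of knockout 2 lay 0.210 of the way from the other knockouts to the controls, and its cell cycle score 0.893 of the way. Pcyt1a thus moved less than that score, but this does not exclude incomplete deletion in knockout 2. Its Pcyt1a, at 7.80, was the highest of the knockouts. The probe set may also read undeleted exons and other cells, and the cell cycle score went with the Paneth score. A different response of that sample stays open too, untested.

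The cell cycle list was called higher in knockouts, with a median of 0.732, by the preset correlation (adjusted p = 0.310 with an estimated correlation, 0.173 by the exact permutation test), and chance stays open. With the Paneth covariate the list median was 0.634 and the shift of the list score was 0.631 (SE 0.113), so the list was higher at a given Paneth score. This does not decide on more crypt tissue in the knockout pieces. The Paneth score differed little between the groups (0.265, SE 0.550), so the covariate could hardly lower the shift. Less muscle in the knockout pieces is argued against by a cell cycle shift that exceeded the enterocyte shift by 0.864 (SE 0.309). An effect of the loss of Pcyt1a stays open as a hypothesis, as does Cre activity, which the design confines to the knockouts and which cannot be told apart from it here.

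The enteroendocrine and hormone lists were called lower in knockouts by the preset correlation (adjusted p = 0.163 for both with an estimated correlation, 0.0778 by the exact permutation test), and chance stays open. Less epithelium in the knockout pieces is not excluded, since the enteroendocrine shift lay only -0.185 (SE 0.148) from the enterocyte shift. Whether the knockout pieces came from a more distal place cannot be told, because the distal minus proximal shift without hormone genes was 0.101 with an SE of 0.293. Loss of Pcyt1a, and Cre activity, stay open and were not tested apart.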

How the results depend on the processing

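The settings with a covariate, the settings without the 3 arrays highest in smooth muscle or the 2 highest in B cell markers, and the exact test of list scores were chosen after seeing the data. No paired analysis was possible because the replicate numbers, 1 to 5 and 6 to 10, do not recur between the groups. Pcyt1a stayed lower and past the threshold in every setting tried, between -2.01 and -1.85 with 1 array left out, and so did Sst.

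The count of called genes was 6, with 1 higher and 5 lower. With 1 array left out it ran from 2 to 452 (0 to 395 higher, 2 to 57 lower). It was 23 (9 higher, 14 lower) at an adjusted p of 0.1 and 2 (0 and 2) at 0.01. It was 2 (0 and 2) with median centring, 5 (0 and 5) with a further quantile normalisation and 10 (3 and 7) with a variance trend and robust fitting. It was 4 (1 and 3) with array weights, 3 (1 and 2) over all probe sets and 6 (2 and 4) at a mean log2 intensity of at least 6. It was 3 (1 and 2) with the smooth muscle covariate, 337 (259 and 78) with the Paneth covariate, and 2 (0 and 2) without the 3 smooth muscle arrays or without the 2 B cell arrays. Fewer samples and stricter thresholds account for part of this by construction, and otherwise the cause was not tested.

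Of the 49 lists 20 were called, against 0 with an estimated correlation, 4 by fry and 0 by the exact permutation test of list scores. The other settings called 17 to 24, and 18 to 23 with 1 array left out. The smooth muscle median of -0.616 ran from -0.913 to -0.0105 with 1 array left out, was -0.0162 with its own covariate, which removes it by construction, and was 0.384 without the 3 arrays. The B and plasma cell median of -0.537 was -0.019 without the 2 arrays, which were chosen for that list. Of 280 other settings of the called lists, 205 kept the call, 72 kept the direction and lost the threshold, and in 3, those of smooth muscle and B cell markers just given, the camera direction turned. The median changed sign in 1 of these, the smooth muscle list without the 3 arrays. Detection values were not used here, so the signal over background of weakly expressed genes was not assessed.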

Other observations

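The overlap described here was examined after the data were seen. Without knockout 2 and with the Paneth covariate, 245 genes were called in both settings, 203 higher and 42 lower in knockouts, all 245 in the same direction. The 2 fits use mostly the same arrays, so a large overlap follows from their design and is not independent evidence. All 6 genes called with all 10 arrays and no covariate were among them.

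The following members of the 245 lie outside the fixed lists and were chosen after their values were seen. With all 10 arrays and no covariate their adjusted p was at least 0.0728. Higher were the antiviral gene Oas1g (1.59 with the covariate, 1.44 without knockout 2), Clca3b (1.29 and 1.64) and the aldo-keto reductase Akr1b8 (1.17 and 1.31). Lower were the basement membrane gene Fras1 (-1.37 and -1.72), the tryptophan-degrading enzyme Ido1 (-0.98 and -1.25), D-amino acid oxidase Dao (-0.82 and -1.13), the deiodinase Dio1 (-0.73 and -0.92) and the growth hormone receptor Ghr (-0.71 and -0.79). Of the 35 cell cycle genes, 26 were called without knockout 2, 18 with the covariate and 17 in both.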
